A study of Homo sapiens with 12 samples.

How the data were processed

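RNA-seq libraries were made from 4 human glioma lines, SF126, SF126R, U118MG and U118MGR, with 3 libraries each and none left out. Per the labels, cells were grown in MEM with 10% fetal bovine serum, RNA was extracted with TRIzol, and poly(A) RNA was captured on oligo-dT beads and made into libraries with the NEBNext Ultra II kit. All libraries carry batch label 1, so no batch could be compared.

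The deposited table holds TPM that the authors computed, 1 column per library, rounded to 2 decimals. Per the labels, fastp 0.23.2, STAR 2.7.10a and featureCounts 2.0.3 of Subread were used with GRCh38/hg38, but the part each played is not given. The annotation release, the strand setting, the gene lengths behind the TPM and any filter are not given in the sources used here. Every column sums to between 999999 and 1000001, which fits the stated unit. TPM keep no read counts, so depth per library is unknown, no count model was used, and no counting interval or floor is given. Gene symbols are those of the table, and positions come from GENCODE release 29 on GRCh38, which matched 56868 of the 60498 genes and 15758 of the 15849 tested.

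Genes at 1 TPM or more in at least 3 of the 12 libraries were tested, 15849 in all, on log2(TPM + 1). A linear model with 1 mean per line was fitted to all libraries with limma 3.58.1 in R 4.3.3 (eBayes with trend, 8 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison. Genes with an adjusted p under 0.05 were called. The comparisons were SF126R against SF126, U118MGR against U118MG, SF126 against U118MG, and the difference between the changes of the 2 pairs as an interaction term. Genes called in the same direction in both pairs were counted beside the number that independent lists would share. KPNA3, MGMT and STAT3 were also given an exact two-sided permutation test of 3 libraries against 3, whose smallest p is 0.1. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

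Gene lists were tested with camera of limma at its preset correlation, adjusted over the 29 lists with at least 5 tested genes, beside camera with an estimated correlation and fry. The 31 lists, with 735 members all found in the table, cover importin and exportin receptors, direct reversal and base excision repair, mismatch repair, homologous recombination and Fanconi anaemia, glioma stem cell markers, JAK-STAT3 components, STAT3 targets, ABC transporters, mesenchymal, proneural and classical glioblastoma genes, S phase, G2 and M phase, p53 targets, interferon, NF-kB, antigen presentation, extracellular matrix, TGF-beta, hypoxia and glycolysis, NRF2, the unfolded protein response, cholesterol synthesis, ribosomal proteins, mitochondrially encoded genes, and markers of astrocytes, oligodendrocytes, neurons, pericytes and fibroblasts, immune and endothelial cells, and epithelium. Members that rose or fell are counted over all genes tested and adjusted over the list alone.

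The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 3 title genes; the 10 largest rises and falls of each pair among called genes with a mean of 10 TPM or more in the higher line and no overlap of libraries; from each list up to 4 called members with the largest change at 5 TPM or more and the 2 most abundant members; up to 10 genes per direction called the same way in both pairs and 5 per direction called in opposite ways, at 10 TPM or more in some line; and 5 per direction between the parental lines. Where fewer are named, those left out come from the end of a ranking, apart from some genes of the rule that are not reported here whatever their values. Genes on the Y chromosome and XIST were never named.

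The alternatives tried were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at 5 TPM, rescaling by median ratio, quantile normalization, rescaling without mitochondrial genes and the top 50 genes, eBayes without trend, array weights, only the 6 libraries of a pair, a replicate block (4 residual degrees of freedom), leaving out each library in turn, an adjusted p under 0.01, and a minimum 2-fold change. One alternative, the U118 lines without the first U118MG library, was added after that library was seen to stand apart. Replicate numbers did not pair libraries, as the deviations of libraries with the same number in 2 lines correlated at -0.048 to 0.025. No 2 libraries were copies of each other: replicates shared at most 835 identical values. The pipeline was tested on simulated data with changes put into 200 genes. In the SF126 pair 43.3% of genes were recovered at 1.5-fold, 79.1% at 2-fold and 97.0% at 4-fold, with 10 false calls among 156. In the U118 pair 50.7%, 80.6% and 90.9% were recovered, with 9 false calls among 157. The simulated noise was independent between genes, with 1 spread per gene for all libraries. The first U118MG library differed more from its replicates (SD of log2 differences 0.817 and 0.822) than those did from each other (0.244). These rates therefore need not hold for the real libraries.

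Runs of neighbouring genes were sought among protein-coding genes at a mean of 5 TPM or more in 1 line, in order of position, as 3 or more in a row under 0.05 TPM in every library of the other line, against 10000 shuffles of gene order. This search was chosen after KPNA3 was seen to be absent from SF126.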

Results

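Gene expression was measured by sequencing poly(A)-selected RNA in 12 libraries from 4 human glioma cell cultures, with 3 libraries each. SF126, which the labels call an astrocytoma line, and U118MG, which they call a glioblastoma line, were untreated. The series describes SF126R and U118MGR as the resistant lines derived from them by 6 months or more under temozolomide. This DNA-alkylating drug is used against glioblastoma. The deposited table gives TPM (transcripts scaled to a common sum), and each library sums to between 999999 and 1000001 TPM. TPM keep no read totals, so the depth of each library is unknown and no counting interval or detection floor can be given. Between 20633 and 24474 genes were above 0 in a library, and between 12800 and 14364 were at 1 TPM or more. Levels are given as mean TPM ± SD over the 3 libraries of a line, and changes as differences in log2(TPM + 1). Nothing in the labels says that numbered replicates were separate cultures. P-values of genes therefore measure the spread between these libraries only, which the model pools over the 4 lines. Camera p-values also rest on the spread between genes, and those of runs on shuffles of gene order.

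The U118MGR libraries resembled their parent line, and the SF126R libraries resembled SF126 hardly more than the 2 parental lines resembled each other. Across the 15849 genes tested, which are not independent replicates, the mean Pearson correlation of log2(TPM + 1) was 0.967 between U118MGR and U118MG libraries. It was 0.864 between SF126R and SF126, 0.845 between SF126 and U118MG, and 0.853 between SF126 and U118MGR. Replicates correlated at 0.992 or more, except that the first U118MG library reached 0.935 with each of its replicates. This library also stood apart on the third principal component, at 76.7 against -12.5 to 0.65 in the other 11 libraries, a component that held 6.0% of the variance. Its KRT18 level, an epithelial keratin, was 316 TPM against 0.10 and 0.03 in the other U118MG libraries. Mitochondrially encoded transcripts took 2.45 to 2.61% of TPM in SF126 and 13.2 to 13.6% in SF126R. In U118MG they took 8.80% in the first library, 17.2% in the second and 14.7% in the third, and in U118MGR 6.09 to 7.84%. FTL, the ferritin light chain, alone took 4.94 to 5.04% of TPM in SF126R.

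**Figure D1:**
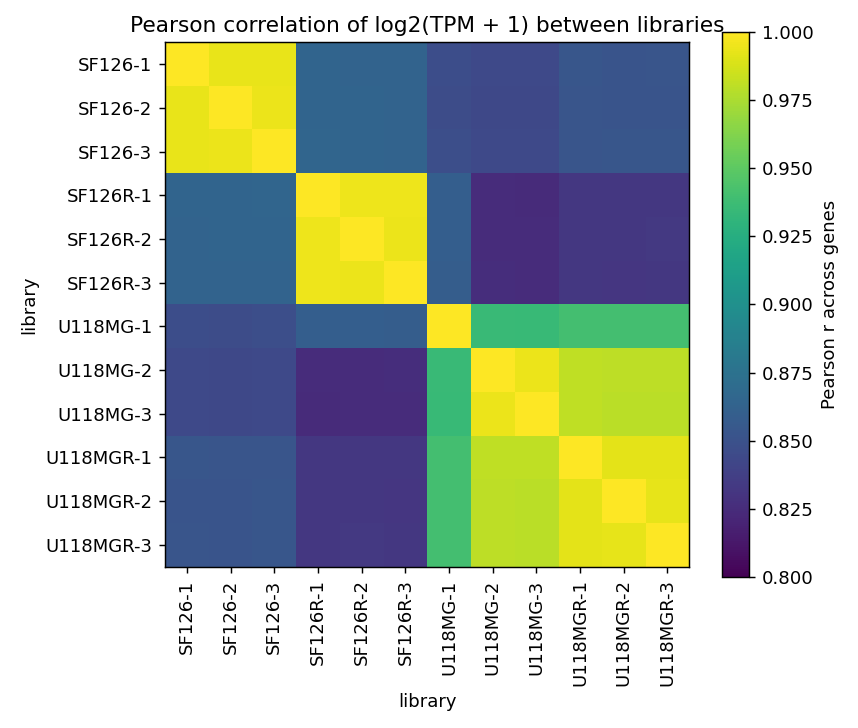
Pearson correlation of log2(TPM + 1) across the 15849 tested genes for each pair of the 12 libraries, with the colour scale giving r. The 3 SF126R libraries correlated with SF126 at a mean of 0.864, and the first U118MG library correlated with its replicates at 0.935 while the other 2 reached 0.994 with each other.

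KPNA3, MGMT and STAT3 are the genes named in the title of the series, which asks whether KPNA3, a nuclear import receptor of the importin alpha family, drives resistance through them. KPNA3 and MGMT were both higher in each resistant line than in its parent, and STAT3 was lower in SF126R and higher in U118MGR. KPNA3 (ENSG00000102753.9, GRCh38 chromosome 13, 49699307 to 49792921) was listed at 0 in all 3 SF126 libraries and at 42.2 ± 1.72 TPM in SF126R (adjusted p = 2.33e-12). With SF126 at 0 the size of that log2 change is set by the pseudocount, at 5.43 with 1, 8.72 with 0.1 and 12.04 with 0.01. KPNA3 rose from 36.4 ± 1.51 TPM in U118MG to 50.1 ± 3.07 TPM in U118MGR, a log2 change of 0.45 (SE 0.071, adjusted p = 0.00144). That change was 0.25 after median-ratio rescaling (adjusted p = 0.043), and its call ended after quantile normalization, at 0.19 (adjusted p = 0.157). MGMT (ENSG00000170430.9, chromosome 10, 129467184 to 129768007), the methyltransferase that removes the O6-methylguanine lesions temozolomide makes, was listed at 0, 0.03 and 0 TPM in SF126 and at 20.3 ± 1.00 TPM in SF126R (adjusted p = 2.34e-11), a log2 change of 4.40, 7.55 or 10.32 with the same 3 pseudocounts. MGMT rose from 4.72 ± 0.24 to 8.52 ± 0.50 TPM in U118MGR, by 0.73 log2 units (SE 0.08, adjusted p = 0.000214). That call ended at a pseudocount of 0.01 (0.85, adjusted p = 0.187), in a fit whose pooled spread includes the SF126 libraries at or near 0. With only the 6 libraries of the pair, at a pseudocount of 1, the call held (adjusted p = 0.0289). STAT3 (ENSG00000168610.14, chromosome 17, 42313324 to 42388568), a transcription factor activated by cytokine receptors, fell from 104.9 ± 0.98 to 68.0 ± 0.60 TPM in SF126R (log2 change -0.62, adjusted p = 0.000281). That call ended when libraries were rescaled by their median ratio, at -0.17 (adjusted p = 0.134). In the U118 pair STAT3 rose from 53.4 ± 8.92 to 67.9 ± 0.29 TPM (0.35 log2 units, adjusted p = 0.0264). The first U118MG library, at 43.2 TPM against 57.6 and 59.4 TPM, set part of that difference, which was 0.21 without it (adjusted p = 0.000252), and the call ended under each of 3 other scalings. It also ended, with the change still at 0.35 to 0.36, with only the 6 libraries of the pair (adjusted p = 0.177), with a replicate block (0.0556) and without U118MGR replicate 1, 2 or 3 (0.0604, 0.0731 and 0.0742). For each of the 3 genes in each pair the libraries of the 2 lines did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The study chose these genes on these samples or others, so they are not independent evidence. STAT3 activation is a matter of protein phosphorylation, which RNA levels do not measure.

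**Figure D2:**
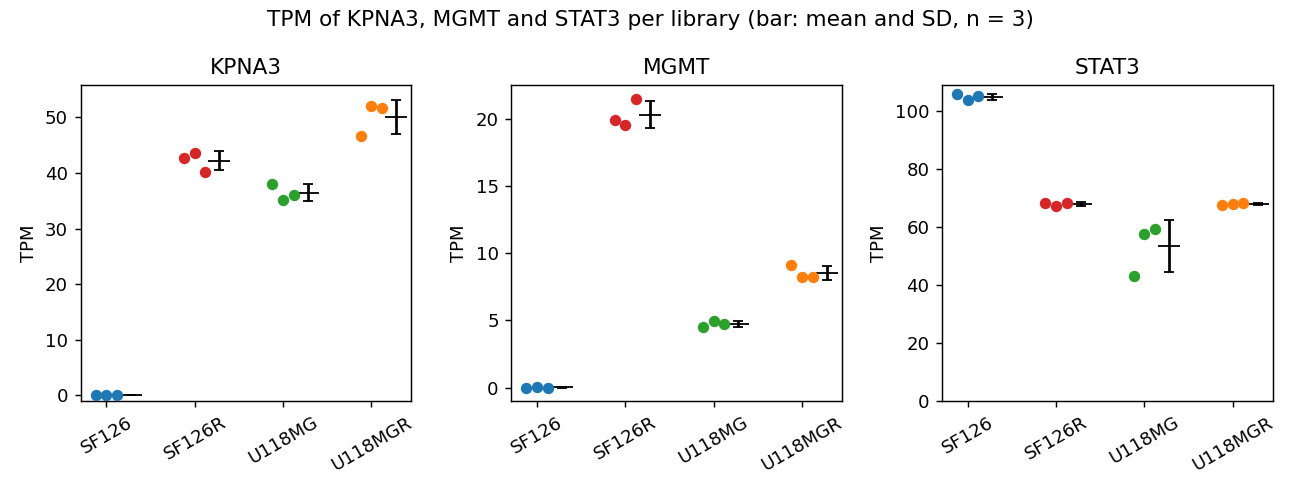
TPM of KPNA3, MGMT and STAT3 in each of the 12 libraries, on linear axes, with points for libraries and black bars for the mean ± SD of 3 libraries. KPNA3 lies at 0 in SF126 and at 42.2 TPM in SF126R, MGMT at 4.72 TPM in U118MG and 8.52 TPM in U118MGR, and STAT3 at 104.9 TPM in SF126 and 68.0 TPM in SF126R.

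SF126R against SF126 asks what differs between a resistant line and the parent named for it, in the first pair. Rises and falls are differences between the libraries of the lines, and whether SF126 and SF126R share an origin stays open, as given below. The aldo-keto reductase AKR1B10 (ENSG00000198074.9) rose from 1.70 ± 0.73 to 2288 ± 24.3 TPM, AKR1C2 (ENSG00000151632.16) from 14.0 ± 0.90 to 7383 ± 24.6 TPM, and the aldehyde dehydrogenase ALDH3A1 (ENSG00000108602.17) from 0.013 ± 0.023 to 177 ± 3.37 TPM. The cytokine IL1B (ENSG00000125538.11) fell from 630.5 ± 3.81 to 0.74 ± 0.18 TPM, and the collagenase MMP1 (ENSG00000196611.4) from 5295 ± 28.4 to 19.1 ± 0.35 TPM. In all, 10756 of 15849 genes passed at an adjusted p under 0.05, 2645 higher and 8111 lower in SF126R, and 976 at least doubled while 4108 at least halved on this scale. The share of rises depends on the scale: the median log2 change over all genes was -0.41, and -0.05 after median-ratio rescaling, which centres the changes and gave 4755 higher and 5565 lower genes. Rescaling without mitochondrial and top 50 genes gave 3652 and 6614, with a median of -0.23. Quantile normalization turned the majority, with 5443 higher and 4827 lower genes and a median of 0.06. The fit pools the spread of all libraries, and without the first U118MG library 12755 genes passed in this pair.

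Other genes with the largest rises in SF126R included further enzymes and secreted factors. The hydrolase CMBL rose from 0.363 ± 0.061 to 177 ± 7.59 TPM, the carboxylesterase CES1 from 2.80 ± 0.26 to 231 ± 8.43 TPM, and the chemokine CXCL12 from 0.623 ± 0.065 to 123 ± 1.15 TPM. The inflammasome adaptor PYCARD rose from 0.047 ± 0.040 to 62.9 ± 6.06 TPM, the protease-activated receptor F2RL2 from 0.68 ± 0.020 to 96.9 ± 3.99 TPM, and the extracellular sulfatase SULF2 from 0.957 ± 0.298 to 102 ± 3.12 TPM. EBPL, a gene next to KPNA3, was listed at 0 in SF126 and reached 84.5 ± 1.02 TPM. Among the largest falls, ALDH7A1 at 279 ± 5.16 TPM and VCX3A at 276 ± 14.0 TPM in SF126 were listed at 0 in SF126R. The decoy receptor IL13RA2 fell from 319 ± 5.50 to 0.27 ± 0.017 TPM, the transglutaminase TGM2 from 289 ± 3.21 to 0.16 ± 0.087 TPM, and the sialic acid receptor SIGLEC15 from 220.2 ± 8.67 to 0.013 ± 0.012 TPM. IER3 fell from 254 ± 8.61 to 0.24 ± 0.16 TPM, the growth factor FGF7 from 203 ± 9.14 to 0.10 ± 0.079 TPM, and CDCP1 from 183 ± 1.68 to 0.04 ± 0.017 TPM. Adjusted p-values of these 20 genes ran from 3.72e-14 for MMP1 to 9.08e-05 for AKR1B10. AKR1C2 and VCX3A have near copies in the genome, and how reads shared between copies were assigned is not given.

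KPNA3 lay at the end of a run of 8 neighbouring genes that were absent from SF126 and expressed in SF126R. The run covers 817 kb of chromosome 13 (48975912 to 49792921) and holds FNDC3A, CDADC1, CAB39L, SETDB2, PHF11, RCBTB1, EBPL and KPNA3. All 8 were listed at 0 in every SF126 library, except FNDC3A with a mean of 0.003 TPM. In SF126R they stood at 11.9 ± 0.85, 12.6 ± 1.28, 10.5 ± 0.41, 5.67 ± 0.70, 9.87 ± 0.54, 14.0 ± 0.62, 84.5 ± 1.02 and 42.2 ± 1.72 TPM in that order. The nearest expressed gene on either side was present in both lines, with RCBTB2 at 2.89 ± 0.15 TPM in SF126 and 2.72 ± 0.31 TPM in SF126R, and SPRYD7 at 7.34 ± 0.33 and 14.7 ± 3.10 TPM. Beyond RCBTB2, LPAR6 was at 0.15 ± 0.20 TPM in SF126 and 3.45 ± 0.55 TPM in SF126R. RB1, the retinoblastoma tumour suppressor on the same arm, stood at 2.12 ± 0.39 TPM in SF126 and 20.3 ± 1.33 TPM in SF126R. Of 9201 protein-coding genes at a mean of 5 TPM or more in SF126R, 25 were under 0.05 TPM in every SF126 library, and 8 of these made up this run. The genes of this paragraph other than KPNA3 and EBPL were chosen after their values were seen.

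**Figure D3:**
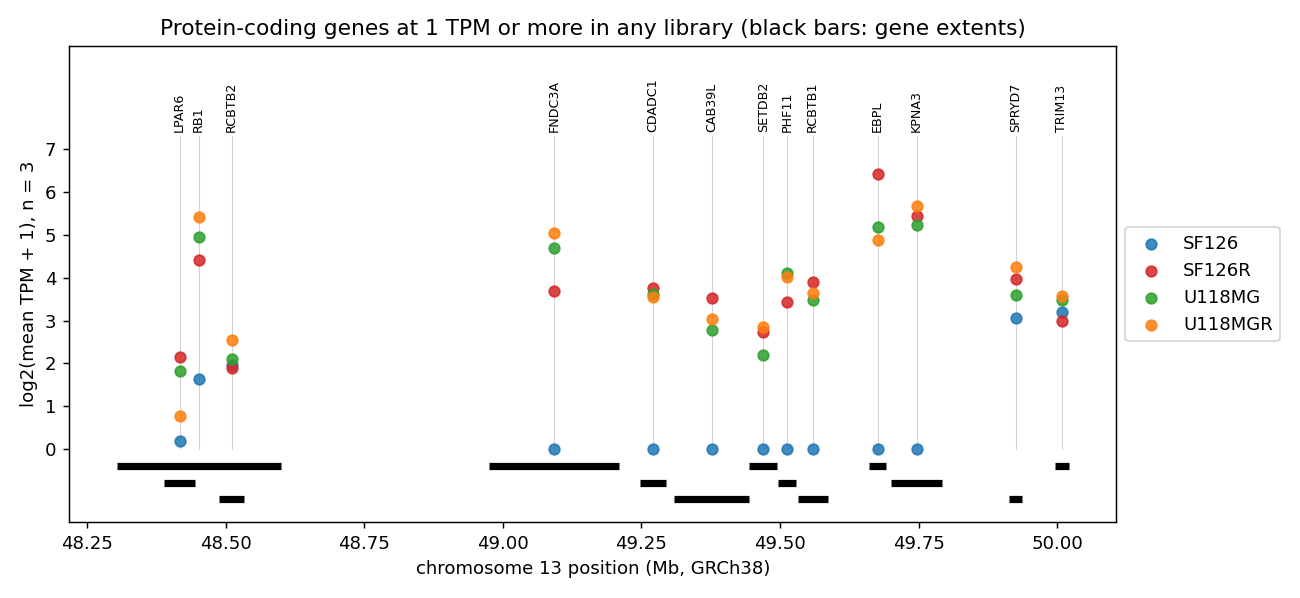
Position on chromosome 13 (Mb, GRCh38) against log2 of the mean TPM + 1 of 3 libraries, with 1 coloured point per line for each protein-coding gene at 1 TPM or more in any library and black bars for gene extents. From FNDC3A to KPNA3, over 817 kb, SF126 lies at 0 while SF126R lies between 5.67 and 84.5 TPM.

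Of 29 gene lists tested in SF126R against SF126, 5 were higher and 5 were lower than the other genes, and none passed with a correlation estimated from the data. Targets of NRF2, the oxidative stress regulator, formed the list with the smallest p-value, with 22 of 23 higher and 1 lower (adjusted p = 7.73e-16, and 0.207 with an estimated correlation). SRXN1, which repairs oxidised peroxiredoxins, rose from 52.7 ± 0.61 to 1168 ± 7.65 TPM and FTL from 3741 ± 45.9 to 49779 ± 563 TPM, while the malic enzyme ME1 was the 1 that fell, from 37.0 ± 0.36 to 0.007 ± 0.006 TPM. All 13 mitochondrially encoded genes rose (adjusted p = 4.42e-11, and 0.35 with an estimated correlation). Among them were MT-ND1 from 283 ± 6.18 to 3742 ± 184 TPM, MT-ND2 from 579 ± 12.7 to 6124 ± 133 TPM and MT-ND4L, which overlaps MT-ND4, from 4991 ± 309 to 21907 ± 1247 TPM. Unfolded protein response genes rose in 17 and fell in 5 of 22 (adjusted p = 8.7e-07, and 0.207 with an estimated correlation). The stress factors ATF3, TRIB3 and ATF4 rose from 3.88 ± 1.13 to 85.5 ± 5.46, from 26.0 ± 1.06 to 147 ± 4.49 and from 197 ± 5.11 to 846 ± 12.4 TPM. The chaperone CALR fell from 1448 ± 4.98 to 921 ± 2.23 TPM, a call that ended after median-ratio rescaling. Cholesterol synthesis genes rose in 14 and fell in 3 of 24 (adjusted p = 4.99e-06, and 0.576 with an estimated correlation). These counts were 17 and 1 after median-ratio rescaling, and 17 and 6 without the first U118MG library. MSMO1 rose from 44.0 ± 0.99 to 279 ± 13.4 TPM and HMGCS1 from 15.3 ± 0.26 to 100.2 ± 2.07 TPM. Ribosomal protein genes rose in 8 and fell in 2 of 35, or 5 and 2 adjusted over the list alone, 26 and 0 after median-ratio rescaling, and 23 and 8 without the first U118MG library (adjusted p = 0.000386, and 0.898 with an estimated correlation). RPS2 rose from 1707 ± 17.3 to 3043 ± 59.2 TPM. Counts adjusted over the list alone equal those over all genes wherever none is given for the list alone.

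The 5 lists that were lower in SF126R covered matrix, interferon, NF-kB, mitosis and hypoxia. Extracellular matrix genes fell in 32 and rose in 1 of 37 (adjusted p = 8.4e-05, and 0.6 with an estimated correlation). The collagens COL8A1 and COL1A1 fell from 558 ± 21.4 to 5.24 ± 0.40 TPM and from 649 ± 23.3 to 10.3 ± 1.94 TPM, the matrix protein POSTN from 141 ± 1.67 to 0.703 ± 0.087 TPM, and SPARC from 5396 ± 63.5 to 1740.4 ± 12.9 TPM. Interferon response genes fell in 29 and rose in 1 of 32 (adjusted p = 0.000386, and 0.576 with an estimated correlation). IFI27 fell from 79.9 ± 2.76 to 6.56 ± 1.89 TPM, IFI6 from 517 ± 57.1 to 53.8 ± 6.59 TPM and BST2 from 873 ± 11.9 to 354 ± 9.37 TPM. NF-kB response genes fell in 19 and rose in 1 of 25 (adjusted p = 0.0314, and 0.898 with an estimated correlation). The prostaglandin synthase PTGS2 fell from 557 ± 5.37 to 2.67 ± 0.12 TPM and the chemokines CCL2 and CXCL8 from 811 ± 12.8 to 15.7 ± 1.34 and from 1714 ± 23.5 to 185 ± 5.88 TPM, while CXCL1 at 139 ± 5.26 TPM in SF126 was listed at 0 in SF126R. Of the G2 and M phase genes 26 fell and 1 rose of 32, or 17 and 4 after median-ratio rescaling (adjusted p = 0.0328, and 0.898 with an estimated correlation). CENPF fell from 51.9 ± 3.24 to 15.3 ± 1.21 TPM and BUB1B from 40.2 ± 1.83 to 12.4 ± 0.43 TPM, whereas the ubiquitin-conjugating enzyme UBE2C rose from 231 ± 5.53 to 318 ± 3.02 TPM. Hypoxia and glycolysis genes fell in 22 and rose in 2 of 30, or 15 and 3 rescaled (adjusted p = 0.0348, and 0.207 with an estimated correlation). The carbonic anhydrase CA9 fell from 306 ± 7.99 to 16.8 ± 0.42 TPM and the aldolase ALDOC from 102 ± 6.29 to 1.08 ± 0.24 TPM. GAPDH stood at 7509 ± 5.47 and 6667 ± 24.7 TPM (adjusted p = 0.46, with the spread pooled over all 4 lines).

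The other 19 lists did not pass in this pair, although single members changed strongly. Importin and exportin receptors rose in 5 (6 adjusted over the list alone) and fell in 13 of 25, against 10 and 6 after median-ratio rescaling (adjusted p = 0.795). KPNA5 fell from 8.01 ± 0.57 to 1.97 ± 0.17 TPM, IPO8 from 22.8 ± 0.12 to 6.92 ± 0.66 TPM and the importin beta KPNB1 from 377 ± 11.9 to 207 ± 6.25 TPM. Base excision and direct reversal repair genes, which include MGMT, rose in 6 and fell in 12 of 24 (8 and 7 rescaled, adjusted p = 0.845). APEX1 fell from 183 ± 2.39 to 102.3 ± 2.695 TPM. Mismatch repair genes, whose loss confers tolerance of methylated DNA, rose in 3 and fell in 15 of 22 (8 and 8 rescaled, adjusted p = 0.879). MLH3 fell from 18.8 ± 0.73 to 5.89 ± 0.50 TPM, and the exonuclease EXO1 rose from 13.9 ± 1.49 to 48.6 ± 1.92 TPM, as did PCNA from 193 ± 2.30 to 259 ± 4.20 TPM. Homologous recombination genes rose in 4 and fell in 15 of 33 (11 and 9 rescaled, adjusted p = 0.879). BRCA2 fell from 19.0 ± 0.93 to 3.14 ± 0.82 TPM and RBBP8 from 78.9 ± 1.33 to 23.8 ± 1.73 TPM. Glioma stem cell markers rose in 3 and fell in 8 of 15 (5 and 5 rescaled, adjusted p = 0.879). ALDH1A3 fell from 736 ± 6.46 to 15.2 ± 1.37 TPM and ITGA6 from 94.6 ± 0.21 to 11.5 ± 0.37 TPM, while MYC rose from 16.9 ± 0.52 to 117.5 ± 1.31 TPM and CD44 from 1143 ± 27.9 to 1635 ± 13.8 TPM.

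JAK-STAT3 pathway components rose in 4 and fell in 11 of 17 in SF126R (5 and 6 rescaled, adjusted p = 0.923). The cytokine IL11 fell from 110 ± 4.53 to 3.30 ± 0.14 TPM and IL6 from 1009 ± 32.3 to 126 ± 5.12 TPM. STAT3 target genes rose in 5 and fell in 14 of 26 (11 and 9 rescaled, adjusted p = 0.909). The adhesion molecule ICAM1 fell from 231 ± 1.40 to 8.46 ± 0.45 TPM and TWIST1 from 78.2 ± 3.19 to 7.16 ± 2.01 TPM. MMP2 stood at 337 ± 4.04 and 305 ± 0.64 TPM (adjusted p = 0.673, with the spread pooled over all 4 lines). ABC efflux transporters rose in 3 and fell in 8 of 19 (adjusted p = 0.923), or 6 and 11 without the first U118MG library, where the test direction turned up (adjusted p = 0.733). The drug exporters ABCG2 and ABCC1 rose from 1.59 ± 0.63 to 16.4 ± 1.92 TPM and from 18.4 ± 0.18 to 115 ± 2.39 TPM, and the lipid exporters ABCG1 and ABCA1 fell from 9.68 ± 0.070 to 0.19 ± 0.072 TPM and from 8.52 ± 0.17 to 0.093 ± 0.075 TPM. Mesenchymal glioblastoma genes rose in 3 and fell in 21 of 30 (adjusted p = 0.101, and 0.0456 without the first U118MG library). ITGA5 fell from 770.4 ± 11.8 to 56.1 ± 0.14 TPM and VIM from 2524 ± 71.8 to 653 ± 20.9 TPM. Proneural genes rose in 2 (3 adjusted over the list alone) and fell in 11 of 15 (adjusted p = 0.537), with NCAM1 from 27.9 ± 1.18 to 0.167 ± 0.091 TPM. Classical genes rose in 4 and fell in 9 of 14 (4 and 5 rescaled, adjusted p = 0.923), with GAS1 from 19.5 ± 0.49 to 0.087 ± 0.051 TPM. S phase genes rose in 8 and fell in 15 of 31, 9 and 16 adjusted over the list alone and 15 and 7 rescaled (adjusted p = 0.662), with UHRF1 from 30.7 ± 1.18 to 8.72 ± 0.31 TPM. Of 27 p53 targets 8 rose and 10 fell (10 and 6 rescaled, adjusted p = 0.358), with FAS from 38.7 ± 0.79 to 5.74 ± 0.73 TPM. Antigen presentation genes rose in 2 (3 adjusted over the list alone) and fell in 13 of 18 (adjusted p = 0.298). HLA-DPB1 fell from 51.4 ± 4.17 to 0.467 ± 0.095 TPM, TAPBP from 222 ± 2.55 to 55.1 ± 2.18 TPM and B2M from 10451 ± 80.9 to 3929 ± 106 TPM. TGF-beta response genes rose in 6 and fell in 10 of 22 (10 and 7 rescaled, adjusted p = 0.374). TGFBI fell from 4253 ± 44.3 to 1160.1 ± 18.2 TPM, a call that ended after rescaling. Camera compares a list with all other genes, whose median was -0.41. The importin, base excision, stem cell, JAK-STAT3, S phase, p53 and epithelial lists had medians under 0 and a test direction of up. The TGF-beta list had a median of 0.00, a mean of -0.42 and the direction up. The JAK-STAT3 and epithelial medians, at -0.61 and -0.45, lay below -0.41, so medians alone do not give the direction. Without the first U118MG library the direction turned down for stem cell markers and JAK-STAT3 (camera adjusted p = 0.889 and 0.784).

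U118MGR against U118MG asks the same question in the second line, where the changes were smaller. The smooth muscle actin ACTG2 (ENSG00000163017.13) rose from 0.357 ± 0.193 to 14.1 ± 2.75 TPM and the actin-bundling protein LCP1 (ENSG00000136167.13) from 10.2 ± 1.21 to 92.0 ± 7.88 TPM. The chemokine receptor ACKR3 (ENSG00000144476.5) fell from 18.9 ± 1.42 to 4.19 ± 1.09 TPM and the fatty acid desaturase FADS2 (ENSG00000134824.13) from 57.0 ± 13.8 to 14.7 ± 1.13 TPM. In all, 4290 genes passed, 3702 higher and 588 lower in U118MGR, of which 199 at least doubled and 84 at least halved (238 and 172 without the first U118MG library). The median log2 change over all genes was 0.17, and 0.00 after median-ratio rescaling, which gave 1305 higher and 1017 lower genes. Without the first U118MG library 7941 genes passed, 6156 higher and 1785 lower, and 4207 of the 4290 were among them in the same direction. With only the 6 libraries of the pair 930 passed, 824 higher and 106 lower, and with a replicate block 3069.

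Further rises in U118MGR were those of SPANXC, a cancer-testis gene with near copies, from 1.05 ± 0.97 to 19.7 ± 4.94 TPM, the pregnancy glycoprotein PSG4, which also has near copies, from 2.05 ± 2.11 to 15.2 ± 0.56 TPM, AK5 from 8.64 ± 3.65 to 46.4 ± 3.98 TPM and BEX1 from 20.3 ± 6.17 to 95.2 ± 7.35 TPM. LRRC38 fell from 10.8 ± 2.96 to 2.19 ± 0.24 TPM and NDUFA4L2 from 12.6 ± 1.31 to 3.06 ± 0.27 TPM. For 8 of the genes with the largest changes the first U118MG library lay far from the other 2. It held 332 TPM of ALDH3A1 against 14.2 and 13.8, 484 of AKR1C3 against 49.7 and 46.3, and 25.0 of PKDCC against 2.55 and 2.97. These genes averaged 3.95 ± 0.26, 16.9 ± 0.32 and 0.467 ± 0.147 TPM in U118MGR, and their log2 changes of -3.09, -2.55 and -2.29 became -1.60, -1.45 and -1.36 without that library. MMP3 at 384 TPM against 32.6 and 33.1, and PPAPDC1A at 11.9 against 0.60 and 0.76, reached 548 ± 9.97 and 18.8 ± 1.68 TPM in U118MGR, and their changes of 2.85 and 2.58 became 4.02 and 3.56. The periplakin gene PPL at 2.23 TPM against 24.6 and 25.8 and the cystatins CST1 at 2.95 against 20.7 and 20.3 and CST2 at 4.27 against 18.1 and 19.9, which are near copies of each other, stood at 1.77 ± 0.30, 0.443 ± 0.107 and 1.36 ± 0.04 TPM in U118MGR. Their changes of -2.24, -3.08 and -2.44 became -3.25, -3.90 and -3.08. Adjusted p-values of the genes named in these 2 paragraphs ran from 2.62e-07 for LCP1 to 0.0329 for ALDH3A1.

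The S phase, importin and exportin, mismatch repair, base excision, and G2 and M phase lists were higher in U118MGR than the other genes, and of these 5 S phase alone also passed with an estimated correlation. S phase genes rose in 18 (21 adjusted over the list alone) and fell in 0 of 31 (adjusted p = 3.34e-05, and 0.0332 with an estimated correlation). The ribonucleotide reductase subunit RRM1 rose from 80.1 ± 14.0 to 137 ± 5.82 TPM and the flap endonuclease FEN1 from 53.7 ± 2.58 to 91.3 ± 5.08 TPM, and PCNA stood at 417 ± 73.5 and 500.4 ± 12.4 TPM (adjusted p = 0.068, and 4.76e-06 without the first U118MG library). Importin and exportin receptors rose in 16 (17 adjusted over the list alone) and fell in 0 of 25, against 9 and 1 after median-ratio rescaling (adjusted p = 0.000201, and 0.162 with an estimated correlation). TNPO1 rose from 93.9 ± 3.05 to 180 ± 15.9 TPM, KPNA2 from 199 ± 41.5 to 321 ± 2.94 TPM and KPNB1 from 218 ± 17.3 to 312 ± 10.5 TPM. Mismatch repair genes rose in 13 and fell in 0 of 22, or 16 and 1 adjusted over the list alone (adjusted p = 0.0103, and 0.304 with an estimated correlation). MSH3 rose from 5.86 ± 0.57 to 9.71 ± 0.49 TPM. Base excision and direct reversal repair genes rose in 11 (14 adjusted over the list alone) and fell in 1 of 24 (adjusted p = 0.041, and 0.162 with an estimated correlation). APEX1 rose from 140.2 ± 10.9 to 198 ± 11.5 TPM and XRCC1 from 37.4 ± 14.1 to 63.1 ± 3.57 TPM. The first U118MG library held 21.2 TPM of XRCC1 against 44.8 and 46.3. G2 and M phase genes rose in 11 and fell in 0 of 32, or 16 and 1 adjusted over the list alone (adjusted p = 0.0245, 0.691 with an estimated correlation, and 0.237 without the first U118MG library). KIF23 rose from 58.2 ± 6.91 to 87.7 ± 6.56 TPM and CDC25C from 9.62 ± 3.11 to 15.6 ± 0.81 TPM, and UBE2C stood at 292 ± 53.8 and 341 ± 5.15 TPM (adjusted p = 0.138). In these lists the first U118MG library lay away from its replicates, at 64.0 TPM of RRM1 against 86.4 and 89.7, 151 of KPNA2 against 224 and 222, and 6.10 of CDC25C against 10.7 and 12.01. Without it S phase genes rose in 27, importins in 20, mismatch repair genes in 16 and base excision genes in 17, and of the G2 and M phase genes 17 rose and 4 fell. After median-ratio rescaling 10 S phase genes rose and 0 fell, against 4 and 1 in mismatch repair, 5 and 1 in base excision repair, and 3 and 1 in G2 and M phase.

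The lists that were lower in U118MGR than the other genes numbered 8. Mitochondrially encoded genes fell in 10 (11 adjusted over the list alone) and rose in 0 of 13 (adjusted p = 5.26e-12, and 0.207 with an estimated correlation). MT-ND1 fell from 2767 ± 368 to 1184 ± 100.3 TPM and MT-ND2 from 4764 ± 1108 to 2026 ± 298 TPM, and MT-ND4L stood at 26081 ± 9744 and 15167 ± 2485 TPM (adjusted p = 0.0719). Ribosomal protein genes fell in 2 and rose in 0 of 35 (adjusted p = 5.79e-09, and 0.433 with an estimated correlation). RPL37 fell from 1171 ± 485 to 611 ± 52.0 TPM and RPS3 from 1678 ± 329 to 1151 ± 121 TPM. In the first U118MG library RPL37 stood at 1729 TPM against 931 and 852, and without that library 8 members rose and 9 fell. Cholesterol synthesis genes fell in 4 and rose in 1 of 24 (adjusted p = 1.53e-05, and 0.433 with an estimated correlation), and in 19 and 1 without the first U118MG library. IDI1 fell from 54.7 ± 5.23 to 33.8 ± 0.75 TPM, HSD17B7 from 18.4 ± 1.92 to 12.04 ± 0.85 TPM and SQLE from 34.9 ± 2.85 to 27.1 ± 0.88 TPM, and FDPS stood at 229 ± 75.8 and 173 ± 8.77 TPM (adjusted p = 0.234). NF-kB response genes fell in 5 and rose in 1 of 25 (adjusted p = 3.52e-05, and 0.488 with an estimated correlation), but without the first U118MG library 11 rose and 7 fell (adjusted p = 0.756). That library held 35.6 TPM of TRAF1 against 15.2 and 15.96, 66.2 of NFKB2 against 33.7 and 34.4, and 1652 of CXCL8 against 73.8 and 72.2, and the U118MGR means were 10.7 ± 0.65, 25.0 ± 4.82 and 257 ± 23.4 TPM. TRAF1 and NFKB2 fell (adjusted p = 0.0242 and 0.0309), and CXCL8 changed by 0.30 log2 units (adjusted p = 0.839), or by 1.80 without that library.

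Classical glioblastoma genes fell in 2 and rose in 0 of 14 in U118MGR (adjusted p = 0.00017, and 0.0332 with an estimated correlation). The growth factor PDGFA fell from 12.5 ± 1.65 to 8.10 ± 1.08 TPM. Antigen presentation genes fell in 3 (5 adjusted over the list alone) and rose in 3 of 18 (adjusted p = 0.0185, and 0.488 with an estimated correlation). HLA-F fell from 5.37 ± 1.14 to 2.56 ± 1.11 TPM, HLA-B from 272 ± 26.5 to 171 ± 11.1 TPM and B2M from 6003 ± 95.6 to 4402 ± 291 TPM. ABC efflux transporters rose in 1 and fell in 0 of 19, and rose in 0 and fell in 1 after rescaling, with a median of -0.02 (adjusted p = 0.0313, 0.162 with an estimated correlation, and 0.401 without the first U118MG library). Of 27 p53 targets 1 rose and 1 fell, 0 and 1 adjusted over the list alone and 0 and 3 rescaled (adjusted p = 0.0313, and 0.162 with an estimated correlation), with a median of 0.00, a mean of -0.03 and the test direction down. The polymerase POLK rose from 19.2 ± 2.12 to 24.4 ± 2.09 TPM and PMAIP1 fell from 91.1 ± 1.504 to 73.9 ± 3.93 TPM. Without the first U118MG library the classical list had 5 genes lower and 1 higher, the antigen presentation list 9 and 3, the ABC list 4 and 6, the p53 list 8 and 7, and the mitochondrial list 12 and 0. After median-ratio rescaling 5 classical, 6 antigen presentation, 8 cholesterol synthesis, 7 ribosomal protein and 5 NF-kB genes fell, and 2 antigen presentation genes and none of the others rose.

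The remaining 16 lists did not pass in the U118 pair. Homologous recombination genes rose in 12 (14 adjusted over the list alone) and fell in 0 of 33 (adjusted p = 0.109). PALB2 rose from 14.0 ± 1.63 to 22.9 ± 3.32 TPM and NBN from 32.5 ± 2.90 to 51.7 ± 5.94 TPM. Stem cell markers rose in 1 and fell in 1 of 15 (adjusted p = 0.253). ID1 rose from 133 ± 9.04 to 175 ± 4.83 TPM and CD44 stood at 887 ± 180 and 1114 ± 17.7 TPM (adjusted p = 0.051). JAK-STAT3 components rose in 2 and fell in 1 of 17, against 1 and 2 rescaled (adjusted p = 0.75). JAK1 rose from 56.4 ± 6.78 to 81.1 ± 2.77 TPM and IL6 stood at 7.03 ± 11.2 and 0.823 ± 0.296 TPM (adjusted p = 0.357). STAT3 targets rose in 6 and fell in 4 of 26, against 0 and 4 rescaled (adjusted p = 0.28). BCL2L1 rose from 113 ± 23.2 to 165 ± 6.79 TPM and CEBPD fell from 8.08 ± 0.87 to 3.90 ± 0.56 TPM. Extracellular matrix genes rose in 13 and fell in 2 of 37, or 15 and 3 adjusted over the list alone (adjusted p = 0.109), with THBS2 from 2.36 ± 0.92 to 12.98 ± 0.29 TPM. Mesenchymal genes rose in 11 (15 adjusted over the list alone) and fell in 0 of 30 (adjusted p = 0.164), with LOX from 126 ± 59.9 to 218 ± 14.8 TPM. Proneural genes rose in 5 and fell in 0 of 15 (adjusted p = 0.429), with TCF12 from 47.6 ± 13.9 to 68.1 ± 5.87 TPM. TGF-beta response genes rose in 6 and fell in 1 of 22, 2 and 2 rescaled (adjusted p = 0.951, and up at 0.00903 without the first U118MG library), with TAGLN from 5.56 ± 1.42 to 16.6 ± 3.88 TPM. Hypoxia and glycolysis genes rose in 6 and fell in 2 of 30, 4 and 7 rescaled (adjusted p = 0.917), with the hexokinase HK2 from 14.3 ± 1.62 to 32.2 ± 0.82 TPM. NRF2 targets rose in 1 and fell in 2 of 23 (adjusted p = 0.217), with AKR1C1 from 233 ± 57.5 to 109 TPM. Interferon genes rose in 7 and fell in 2 of 32 (adjusted p = 0.993), with RSAD2 from 5.47 ± 2.12 to 2.63 ± 0.19 TPM. Unfolded protein response genes rose in 11 and fell in 1 of 22, 2 and 2 rescaled (adjusted p = 0.155). CRELD2 rose from 28.2 ± 4.17 to 45.8 ± 2.88 TPM and ATF3 fell from 44.1 ± 33.8 to 13.9 ± 0.91 TPM. The first U118MG library held 195 TPM of LOX against 89.9 and 92.0, 31.6 of TCF12 against 55.9 and 55.4, 19.96 of IL6 against 0.66 and 0.46, and 83.2 of ATF3 against 25.7 and 23.5. The JAK-STAT3, STAT3 target, interferon, TGF-beta, hypoxia and pericyte lists had medians and means above 0 and the test direction down. The stem cell, NRF2 and astrocyte lists had medians above 0, means under 0 and also the direction down. The median over all genes was 0.174. The JAK-STAT3, TGF-beta, NRF2 and pericyte medians, at 0.193, 0.195, 0.181 and 0.265, lay above it, so medians alone do not give the direction. Without the first U118MG library the counts of rises and falls were 17 and 14 for matrix genes, whose median went from 0.50 to 0.06 and whose test direction turned down, and 12 and 5 for NRF2 targets, with a median of 0.31 and the direction up. Leaving it out also gave 19 and 0 in homologous recombination, 6 and 7 in stem cell markers, 7 and 1 in JAK-STAT3, 19 and 4 in mesenchymal, 7 and 3 in proneural, 16 and 3 in TGF-beta, 15 and 3 in hypoxia, 13 and 4 in unfolded protein response, and 7 and 8 in interferon genes, with the direction turned up for JAK-STAT3 and hypoxia and down for proneural genes. Rescaling by median ratio gave 4 and 2 in homologous recombination, 8 and 3 in matrix, 3 and 1 in mesenchymal, and 0 and 3 in NRF2 genes.

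**Figure D4:**
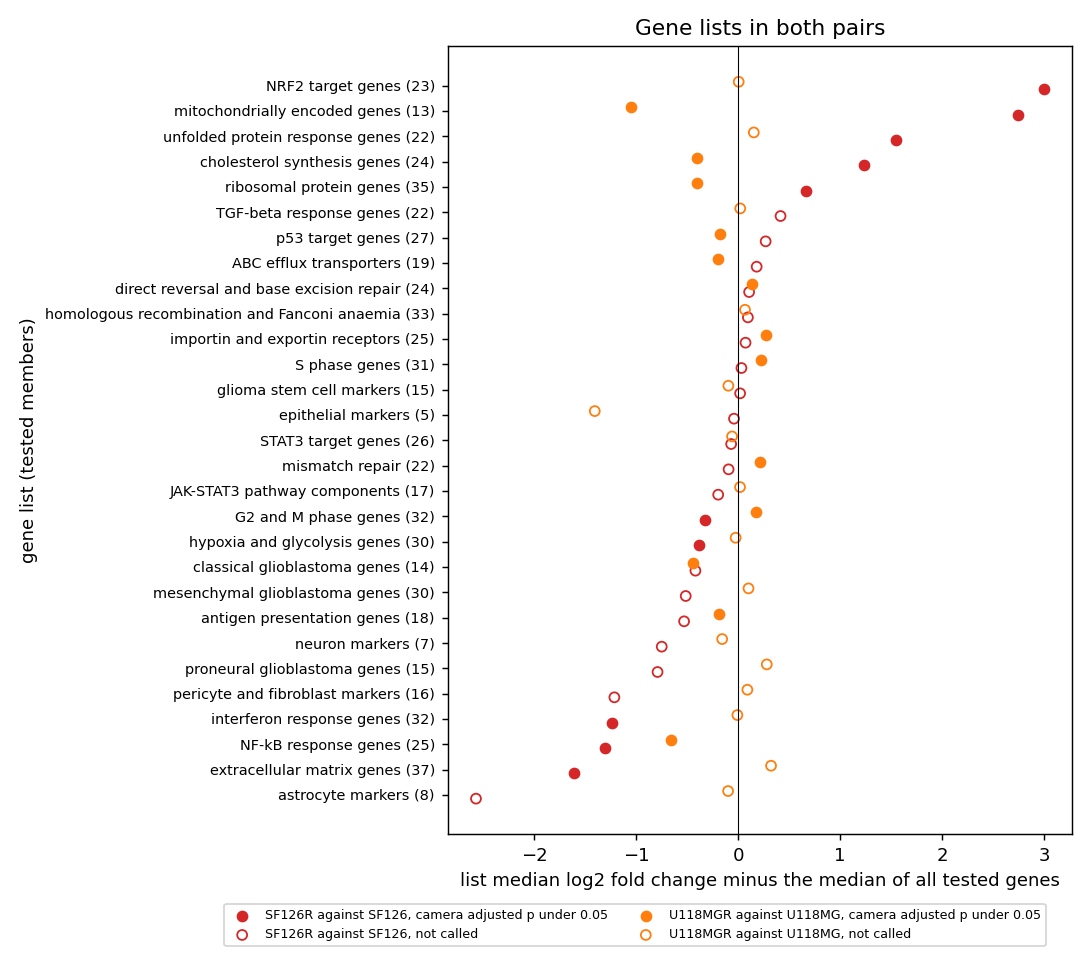
Median log2 fold change of each of the 29 tested gene lists minus the median of all tested genes (x axis), in red for SF126R against SF126 and in orange for U118MGR against U118MG, with filled points for lists that passed camera at an adjusted p under 0.05 with its preset correlation. NRF2 targets lie at 3.00 and mitochondrially encoded genes at 2.74 in SF126R, against 0.01 and -1.05 in U118MGR.

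In the main fit the resistant lines shared no more changes than independent lists would, and the counts rose without the first U118MG library. Called in the same direction in both were 602 genes higher and 256 lower, where independent lists would share 618 and 301. After median-ratio rescaling 417 were higher and 340 lower, for which the number from independent lists was not computed. Without the first U118MG library the shared genes numbered 1573 higher, with 1339 from independent lists, and 1072 lower, with 1048. Among genes higher in both, the GTPase RAC2 rose from 21.8 ± 2.20 to 94.1 ± 2.36 TPM in SF126R and from 0.233 ± 0.125 to 2.24 ± 0.32 TPM in U118MGR. PSG4 reached 40.3 ± 0.64 TPM from 0.563 ± 0.383 in SF126R, and AK5 25.6 ± 8.06 TPM from 8.49 ± 1.10. The antisense RNA RNF185-AS1, for which the strand setting of the counting is not given, rose from 7.15 ± 1.06 to 35.9 ± 7.87 TPM and from 10.1 ± 1.58 to 25.9 ± 13.8 TPM, where its call in the U118 pair (adjusted p = 0.0444) ended under 19 of the alternatives tried. The channel subunit LRRC8E rose from 2.80 ± 0.44 to 6.34 ± 0.44 and from 7.51 ± 1.45 to 17.0 ± 0.35 TPM. Among genes lower in both, NDRG2 fell from 11.97 ± 0.97 to 4.16 ± 0.084 TPM in SF126R and from 6.23 ± 3.27 to 1.72 ± 0.72 TPM in U118MGR, and TSPAN14 from 174 ± 2.41 to 26.4 ± 1.503 and from 25.3 ± 7.72 to 9.42 ± 1.64 TPM. CPT1C fell from 36.9 ± 2.38 to 15.4 ± 0.19 TPM and from 8.07 ± 1.05 to 3.18 ± 1.07 TPM, and in U118MGR ALDH1A3 fell from 2.28 ± 1.15 to 0.427 ± 0.163 TPM and TGM2 from 24.9 ± 8.70 to 10.7 ± 0.13 TPM. Across the 15849 genes, which are not independent replicates, the log2 changes of the 2 pairs correlated at r = -0.118 (Spearman -0.102), and at -0.010 (Spearman 0.053) without the first U118MG library. Among the 11840 genes called in either pair r was -0.097 (Spearman -0.027), and 0.011 (Spearman 0.124) without the first U118MG library.

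The change itself differed between the pairs for 10203 genes, 1890 in favour of SF126R and 8313 of U118MGR. Median-ratio rescaling gave 4139 and 4953, and quantile normalization 4604 and 4407, which turned the majority. KPNA3 and MGMT rose more in SF126R, with interaction terms of 4.98 (adjusted p = 1.45e-10) and 3.67 (adjusted p = 2.08e-09), sizes that the pseudocount sets since SF126 lies at or near 0. STAT3 differed by -0.97 (adjusted p = 0.000158), which was -0.32 after rescaling (adjusted p = 0.0575). Called in opposite directions were 156 genes higher in SF126R and lower in U118MGR and 2192 lower in SF126R and higher in U118MGR, where independent lists would give 98 and 1895. Without the first U118MG library these were 400 and 3667, with 388 and 3615 from independent lists. ALDH3A1, AKR1C3 and CMBL rose in SF126R, AKR1C3 from 66.1 ± 1.49 to 1064 ± 8.66 TPM, and fell in U118MGR, CMBL from 1.32 ± 1.15 to 0.277 ± 0.134 TPM, where the first U118MG library held 2.65 TPM of CMBL against 0.69 and 0.63. The mitochondrial 12S RNA MT-RNR1 rose from 203 ± 11.4 to 4082 ± 64.2 TPM and fell from 794 ± 18.9 to 314 ± 32.1 TPM. MMP1 rose from 141 ± 6.81 to 555 ± 9.12 TPM in U118MGR, POSTN from 31.3 ± 22.3 to 101 ± 13.7 TPM, with 5.54 TPM in the first U118MG library against 43.3 and 45.04, and COL13A1 from 0.793 ± 0.281 to 7.24 ± 0.35 TPM. In SF126R COL13A1 fell from 97.8 ± 1.92 to 0.903 ± 0.216 TPM and LCP1 from 32.9 ± 0.085 to 0.697 ± 0.201 TPM, and BEX1 at 126 ± 7.03 TPM in SF126 was listed at 0. In the U118 pair the calls of CMBL and POSTN ended after median-ratio rescaling (adjusted p = 0.0613 and 0.0533). Of the 29 lists 8 differed between the pairs. NRF2 targets (adjusted p = 1.18e-17), mitochondrially encoded (1.4e-14), ribosomal protein (4.24e-08), cholesterol synthesis (2.34e-08) and unfolded protein response genes (2.75e-05) changed in favour of SF126R, and extracellular matrix (4.06e-05), interferon (0.00162) and G2 and M phase genes (0.00809) in favour of U118MGR. With an estimated correlation their adjusted p-values were 0.209, 0.209, 0.688, 0.424, 0.209, 0.688, 0.688 and 0.72 in that order.

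**Figure D5:**
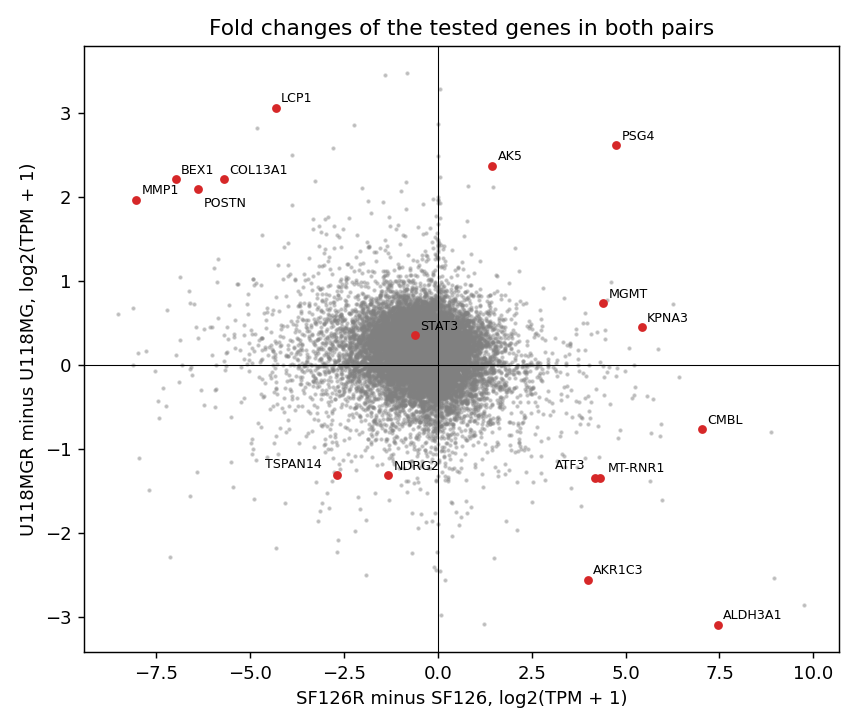
Log2 fold change of the 15849 tested genes in SF126R against SF126 (x axis) and in U118MGR against U118MG (y axis), with 1 point per gene and named genes marked. The points show no common trend (r = -0.118), with KPNA3 and MGMT far to the right and MMP1 at -8.05 on the x axis and 1.97 on the y axis.

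The parental lines, compared for context, differed in 10420 genes, 6635 higher in SF126 and 3785 higher in U118MG. Median-ratio rescaling gave 5464 and 4725, and quantile normalization 4936 and 5384, which turned the majority. SF126 held more of the cytokines IL6, at 1009 ± 32.3 against 7.03 ± 11.2 TPM, and IL1B, at 630.5 ± 3.81 against 1.93 ± 1.15 TPM, and of FGF7 and ALDH1A3, at 203 ± 9.14 against 0.12 ± 0.089 TPM and 736 ± 6.46 against 2.28 ± 1.15 TPM. VCX3A was listed at 0 in U118MG. The fatty acid binding protein FABP3, at 148 ± 82.8 TPM in U118MG, was listed at 0 in SF126, where MFAP2, FAM180A, AJAP1 and FZD6 were at 0.023 ± 0.040, 0.16 ± 0.11, 0.007 ± 0.012 and 0.017 ± 0.015 TPM against 149 ± 79.5, 115 ± 4.42, 90.2 ± 39.2 and 76.8 ± 4.21 TPM. FABP3 was at 52.6 TPM in the first U118MG library against 194 and 198 in the others. STAT3 was higher in SF126 by 0.97 log2 units (adjusted p = 1.05e-05), and KPNA3 and MGMT were lower (adjusted p = 3.46e-12 and 1.21e-09). To follow each derivative's line of origin, genes at 10 TPM or more in all libraries of 1 parent and under 0.1 TPM in all of the other were counted. All 16 U118MG-specific genes (100%) and 0 of 33 SF126-specific genes were at 1 TPM or more in U118MGR. SF126R held 11 of the 33 SF126-specific genes (33.3%) and 8 of the 16 U118MG-specific genes. With limits of 5 and 0.5 TPM the order of these shares turned, at 66 of 156 (42.3%) and 14 of 55 (25.5%). At the first limits, FNDC3A, CDADC1, PHF11, EBPL and KPNA3, all in the run absent from SF126, are among the 8 genes. The 8 therefore do not measure likeness to U118MG over separate loci. The limit of 0.1 TPM also held for the first U118MG library. Of 70 SF126 genes under 0.1 TPM in all other U118 libraries, 33 were at 1 TPM or more in it.

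Markers of other brain and stromal cells were also followed. In SF126R astrocyte markers fell in 7 and rose in 1 of 8 (adjusted p = 0.141), with the glutamate transporter SLC1A3 from 57.2 ± 3.22 to 1.73 ± 0.15 TPM. Neuron markers fell in 5 and rose in 1 of 7 (adjusted p = 0.571), with SYT1 at 23.6 ± 2.13 TPM in SF126 and listed at 0 in SF126R. Pericyte and fibroblast markers fell in 10 and rose in 2 of 16 (adjusted p = 0.205), with ANPEP from 76.6 ± 2.88 to 0.167 ± 0.105 TPM. In U118MGR astrocyte markers rose in 1 and fell in 2 of 8 (adjusted p = 0.253). Neuron markers rose in 2 of 7 (adjusted p = 0.683), with SNAP25 from 3.34 ± 0.16 to 9.60 ± 0.66 TPM. Pericyte markers rose in 5 and fell in 4 of 16, 5 and 5 adjusted over the list alone and 1 and 5 rescaled (adjusted p = 0.109, and 0.018 without the first U118MG library). S100A4 fell from 596 ± 292 to 224 ± 9.97 TPM. Epithelial markers had 5 tested genes, of which 1 fell in SF126R (adjusted p = 0.879) and none passed in U118MGR (adjusted p = 0.109). KRT18 stood at 59.1 ± 3.44 TPM in SF126 and 67.9 ± 1.71 TPM in SF126R (adjusted p = 0.929), and KRT8 at 44.4 ± 0.58 and 32.3 ± 3.00 TPM (adjusted p = 0.776). The first U118MG library widens the pooled spread behind these p-values, which were 0.013 and 0.0258 without it, where 3 of the 5 markers fell and 1 rose in SF126R. In the first U118MG library KRT18 was at 316 and KRT8 at 236 TPM, against 0.20 ± 0.057 and 3.07 ± 0.82 TPM in U118MGR. Oligodendrocyte markers, with 4 of 11 genes tested, and immune and endothelial markers, with 4 of 16, were too few to test as lists. The most abundant of these were CNP, at 36.9 to 91.7 TPM, and CD68, at 32.0 to 227 TPM over the 12 libraries.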

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

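Chosen only after the result was seen were the tests of RNA of other cells and of private genes in the first U118MG library, the share of U118 RNA that single genes allow in SF126R, the length of the run of absent genes, and the counts over other splits of the libraries. The remaining tests of the 2 patterns below were set out after the pattern was seen and before their own results were.

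SF126R differed from SF126 in 10756 genes, about as many as the 10420 between the unrelated parental lines, with KPNA3 listed at 0 in every SF126 library. The scale of TPM is argued against as the cause, since the lowest count under 3 other scalings was 10266 genes. RNA of the U118 lines in the SF126R libraries is argued against too. KPNA3 at its level would need 95.2% of U118 RNA where BCHE, LUM and MFAP2 allow 0.0, 0.0 and 0.01%. Of 14 U118 genes absent in SF126, 6 were above 1 TPM in SF126R (42.9%, under the 50% set beforehand but from too few genes to separate from it). That share decides nothing, since FNDC3A, CDADC1, PHF11, EBPL and KPNA3, all in the run that raised the question, are among the 6. A candidate explanation that stays open is that the SF126 and SF126R libraries come from cells of different origin, as a derivative cannot regain a deleted region: 1 run of neighbouring genes was absent in SF126 and expressed in SF126R (permutation p = 0.0002), which 1 of 10000 shuffles matched, so the prediction of more runs than in any shuffle was not met, although the run held 8 genes and the longest in shuffles 3. A rare SF126 cell that had kept the region, or silencing of the region in SF126 that was lifted in SF126R, could leave the same run. No DNA was measured, and a change acquired under temozolomide, which the design names, was not tested apart from these. For the question of origin only this run was weighed. CDKN2B was also listed at 0 in SF126 and at 36.4 TPM in SF126R, while its neighbour MTAP was expressed in both. In the reverse direction 135 genes were expressed in SF126 and absent from SF126R. How far each explanation covers these genes was not tested.

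The first U118MG library stood apart from the other 2, with 316 TPM of KRT18 against 0.10 and 0.03. A swapped label is argued against, since all 10 genes specific to the U118 lines (100%) were above 1 TPM in it and no library of another line was out of place. RNA of the SF126 or SF126R libraries cannot account for 101 genes at 1 TPM or more that were under 0.1 TPM in all other libraries (12 to 20 such genes in each of those), while the shares of SF126-specific and SF126R-specific genes above 1 TPM, 47.1% (33 of 70) and 60.9% (28 of 46), lay on either side of the 50% set beforehand. A test for RNA of other cells decided nothing: of 2913 genes at 50 TPM or more in its replicates, 0.65% lay below 0.5 times the 5th percentile of its own ratio to them, a limit that few genes can pass in any library, and 0.03% did between the replicates themselves. RNA of other cells and a different state of the U118MG cells both stay open, and no biological explanation was tested.

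The changes of the title genes differed between the pairs, by 4.98 log2 units for KPNA3, 3.67 for MGMT and -0.97 for STAT3 (SF126 pair minus U118 pair), where the pseudocount sets the sizes for KPNA3 and MGMT, which lay at or near 0 in SF126. Among genes called in opposite directions the differences were 10.54 for ALDH3A1 (9.05 without the first U118MG library), 7.79 for CMBL, 6.54 for AKR1C3 (5.44 without that library), 5.67 for MT-RNR1 and 5.52 for ATF3. They were -10.01 for MMP1, -9.19 for BEX1, -8.48 for POSTN (-7.55 without that library), -7.92 for COL13A1 and -7.38 for LCP1. Adjusted p-values of the difference were 1.18e-17 for NRF2 targets, 1.4e-14 for mitochondrially encoded genes, 4.24e-08 for ribosomal protein genes, 2.34e-08 for cholesterol synthesis and 2.75e-05 for the unfolded protein response, all higher in the SF126 pair. They were 4.06e-05 for extracellular matrix, 0.00162 for interferon response and 0.00809 for G2 and M phase genes, all lower in the SF126 pair, and none of the 8 passed with an estimated correlation (adjusted p from 0.209 to 0.72).

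Other splits of the same libraries were counted. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05: 1 split, the real one, gave 10756 genes in the SF126 pair and the highest other 1, the U118 pair gave 4290 and 3, and the parental lines 10420 and 1. For both pairs together 100 of 200 splits, which include those with the U118 labels exchanged, were drawn. The difference between the pairs reached 10203 genes in 1 of the 100, the real one, and the highest other count was 8833. This decides nothing about the U118 labels, since the 12 splits that kept SF126 and SF126R apart, too few for a share under 0.05, all gave 6961 or more genes and the splits that mixed them at most 24. Genes changed the same way reached 858 in 1 of the 100, the real one, and 0 in the others, but this decides nothing, since the mixed splits of a pair alone called at most 3 genes and the real split with U118 labels exchanged, which was not drawn, gave 2348.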

How the results depend on the processing

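The alternative with the U118 lines alone, without the first U118MG library, was chosen after that library was seen; it called 6320 genes, and all other alternatives were planned. A turn of direction was counted as reversed only where either value was called, and as kept where neither was. Of 208 changes of named genes, 152 were kept by this rule, on the same side of the threshold, under every alternative, and none reversed. Most others changed side in a fit of only the 6 libraries of a pair (42), at an adjusted p under 0.01 (24) or without U118MGR replicate 3 (19). Of title gene values under alternatives 135 kept their call and 12 lost it. Of list values 1447 were kept, 41 gained a call, 56 lost it and 16 reversed. The 1447 include lists whose direction turned while uncalled, such as matrix genes in the U118 pair without the first U118MG library. Depth is unknown, so its limit on low values could not be assessed. Where a value changed, the cause was not tested unless given here.

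Fewer genes pass a minimum 2-fold change by construction: 5084 in the SF126 pair, 283 in the U118 pair, 6255 for the difference, 4463 between the parents and 21 changed the same way. Stricter calls at an adjusted p under 0.01 gave 2225 genes in the U118 pair and 396 the same way. Counts in the U118 pair were 2322 by median ratio, 2164 by quantiles, 2485 without mitochondrial and top 50 genes, 9116 with array weights, where the first U118MG library weighed 0.021, and 930 with only the 6 libraries of the pair. Genes changed the same way numbered 3038 with array weights, 206 with 6 libraries and 570 with a replicate block. The correlation of changes was -0.07 at a pseudocount of 0.1, -0.035 at 0.01, -0.166 without a filter and -0.011 with array weights.

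Leaving out 1 library at a time gave 9878 to 12755 genes in the SF126 pair, 2866 to 7941 in the U118 pair, 9575 to 12099 for the difference, 9469 to 12363 between the parents, 593 to 2645 the same way, and correlations of -0.149 to -0.01. The highest counts and the correlation nearest 0 came without the first U118MG library, and the lowest U118 count without U118MGR replicate 2. With pseudocounts of 0.1 and 0.01 the SF126-pair changes were 8.72 and 12.04 for KPNA3 and 7.55 and 10.32 for MGMT, against 5.43 and 4.40, since SF126 lay at or near 0. When libraries were left out, title gene changes ran from 5.41 to 5.46 for KPNA3, 4.36 to 4.43 for MGMT and -0.63 to -0.61 for STAT3 in the SF126 pair. In the U118 pair they ran from 0.42 to 0.50, 0.69 to 0.76 and 0.21 to 0.44, and the STAT3 call ended without U118MGR replicate 1, 2 or 3 (adjusted p = 0.0604, 0.0731 and 0.0742). Lists called ranged from 10 to 11, 11 to 14 and 8 to 12 in the SF126 pair, the U118 pair and the difference.

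STAT3 in the SF126 pair was -0.17 by median ratio (adjusted p = 0.134). In the U118 pair KPNA3 was 0.19 by quantiles (0.157) and MGMT 0.85 at a pseudocount of 0.01 (0.187). STAT3 there was 0.15 by median ratio (0.312), 0.093 by quantiles (0.513), 0.21 without mitochondrial and top 50 genes (0.25), and 0.355 with 6 libraries (0.177), with a replicate block (0.0556) and at an adjusted p under 0.01 (0.0264). With an estimated correlation camera called 0, 2 and 0 lists in the SF126 pair, the U118 pair and the difference, and fry called 25 and 27 in the first and last.

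Fry tests members against no change and camera against other genes, so the directions of these tests can differ. Fry gave adjusted p-values in the SF126 pair of 3.99e-06 for stem cell markers, 8.58e-07 for JAK-STAT3, 1.42e-06 for S phase, 8.47e-07 for p53 and 0.00961 for TGF-beta. In the U118 pair it gave 0.0103 for JAK-STAT3, 0.0378 for STAT3 targets and 3.87e-05 for hypoxia, and leaving out 1 library put the TGF-beta response genes between 0.00903 (up, without U118MG replicate 1) and 0.976 (without U118MGR replicate 3). For the difference fry gave 1.9e-05 for stem cell markers, 2.25e-06 for JAK-STAT3, 1.52e-07 for STAT3 targets, 1.59e-06 for ABC transporters, 3.65e-05 for classical genes, 1.44e-05 for p53 and 0.00422 for TGF-beta. With wider limits SF126-specific genes were present in 42.3% in SF126R and 5.8% in U118MGR, and U118MG-specific genes in 25.5 and 100%, which turned the order in SF126R, and no share changed when 0.5 TPM counted as present.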

Other observations

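All counts of runs and the regions described here were looked at after the run around KPNA3 was seen, and the genes were chosen after their values were seen. The reverse pattern, genes expressed in SF126 and absent from SF126R, was also found. Of 10389 protein-coding genes at a mean of 5 TPM or more in SF126, 135 were under 0.05 TPM in every SF126R library, and they formed 2 runs of 3 or more neighbours (permutation p = 0.0003). On chromosome 1, DMRTA2, FAF1 and CDKN2C (50417550 to 50974633, 557 kb) stood at 8.51 ± 1.08, 86.0 ± 1.69 and 98.3 ± 3.40 TPM in SF126 and at 0.00, 0.007 and 0.00 TPM in SF126R. CDKN2C encodes an inhibitor of the cyclin D kinases CDK4 and CDK6, and FAF1 a FAS-associated factor. The next expressed gene on the far side, RNF11, was at 216 ± 13.9 TPM in SF126 and 194 ± 13.9 TPM in SF126R. On the X chromosome, the cancer-testis genes MAGEA2B, CSAG1, MAGEA12 and MAGEA2 (152714586 to 152753884, 39 kb) stood at 7.48 ± 3.28, 83.0 ± 2.93, 64.0 ± 2.17 and 8.35 ± 3.41 TPM in SF126 and at 0.00 to 0.01 TPM in SF126R, and MAGEA2 and MAGEA2B are near copies of each other. Between U118MG and U118MGR no run of 3 was found in either direction.

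The 9p region around the CDKN2B cell cycle inhibitor also differed between the lines. CDKN2B was listed at 0 in every SF126, U118MG and U118MGR library and at 36.4 ± 0.97 TPM in SF126R. MTAP, the neighbouring methylthioadenosine phosphorylase gene, was at 28.1 ± 0.58 TPM in SF126, 39.46 to 44.81 TPM in SF126R and 0.00 in U118MGR. FOCAD and KLHL9, farther along the arm, were listed at 0 in U118MGR and in U118MG replicates 2 and 3, and at 1.62 and 2.53 TPM in the first U118MG library. They were at 8.60 ± 0.64 and 12.8 ± 0.28 TPM in SF126 and at 3.93 ± 0.087 and 10.5 ± 0.22 TPM in SF126R.

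The first U118MG library also held transcripts that its replicates lacked or held at low levels. GPX2, a glutathione peroxidase, was at 163 TPM in it and under 0.1 TPM in all 11 others. The keratins KRT19 and KRT7 were at 40.1 and 140.2 TPM against 0.00 and 2.53 to 3.60 TPM in its replicates, and CDH1 was at 3.92 TPM against 0.00.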
